A study of Mus musculus with 12 samples.

How the data were processed

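The series profiled hearts of mice 7 days after myocardial infarction, the death of heart muscle that follows blockage of a coronary artery. Mice with a conditional knockout (CKO) of Serpina3n, a secreted inhibitor of serine proteases, were compared with wild-type (WT) mice; per the labels, CKO animals carried a Cre recombinase and WT animals did not. Which cells express the Cre, and which exons it removes, is not given in the sources used here. There were 12 libraries in 4 groups of 3: single cells from WT and CKO hearts, and single nuclei from WT and CKO hearts. The labels give injured heart tissue as the source of the cells and of the nuclei. Replicate numbers are names given in accession order and pair no samples. The labels do not say whether the 3 libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be partly technical. The labels give no date or batch.

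Per the labels' protocols, cells were freed with liberase TH at 0.1 µg/ml and live cells were sorted by Calcein AM staining at 10 µM. For nuclei, dissected injured regions were lysed and filtered at 100 and 20 µm. Both used the 10x Genomics 3' gene expression kit, version 3.1, in which each transcript is read next to its poly(A) tail and carries a unique molecular identifier (UMI). Per the submitters' processing notes, Cell Ranger was run against mm10; its version is not given there. The authors deposited matrices of whole UMI counts per gene and barcode, with no normalization. The annotation held 31053 genes in the cells libraries and 32285 in the nuclei libraries. The barcodes were used as deposited; the lowest total per barcode was between 500 and 897 UMIs, depending on the library. Gene positions were taken from GENCODE release M21 on GRCm38, the assembly also called mm10.

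Barcodes were kept with at least 500 genes and at most 20% mitochondrial UMIs in cells, and with at least 300 genes and at most 10% in nuclei; 79.9% to 86.6% of barcodes per cells library and 92.3% to 100.0% per nuclei library passed. Doublet scores came from scrublet, run within scanpy, and the highest-scoring barcodes were left out at a rate of 0.8% per 1000 barcodes, which removed 4.12% to 11.1% of the passing barcodes of a library. Clustering was run for each assay on log-normalised counts of 2000 variable genes, without Serpina3n, sex-linked and mitochondrial genes, with 30 principal components, 15 neighbours and Leiden resolution 1. This gave 32 clusters of cells and 21 of nuclei. A cluster was given a class from marker lists of 17 cell types when at least 3 markers were at least 2-fold above the other clusters and detected in at least 10% of its barcodes, no other class came close, and under 50% of its barcodes were called doublets. These naming thresholds were set after the clusters were seen. They left 7 clusters of cells and 6 of nuclei unnamed, which held 11.7% ± 12.7 of WT and 7.29% ± 1.61 of CKO cells (26.3% of WT replicate 2, against 3.32% and 5.56% of WT replicates 1 and 3), and 6.04% ± 0.263 of WT and 4.94% ± 1.56 of CKO nuclei (SD, n = 3 each). Classes are called by the name of the marker list, and stand for fibroblast-like cells and so on.

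Barcodes are not replicates, so the counts of a class were summed per library and tested across libraries. Each library had to hold at least 20 barcodes of a class that was tested. Not every class that met this was tested: mural cells, with at least 91 cells and 245 nuclei per library, and the smaller classes were not. The main test was edgeR's quasi-likelihood test with TMM scaling, edgeR's own filter on low counts and Benjamini-Hochberg adjustment, at an adjusted p of 0.05. Fibroblasts were tested in cells, in nuclei, in both with the assay as a term, and for the assay by genotype interaction; macrophages and endothelial cells were tested in each assay and cardiomyocytes in nuclei. Lists of genes, 32 in number, and the marker lists were fixed with the tests before the data were examined, and were tested with limma's camera at a preset inter-gene correlation of 0.01 when at least 5 members were tested, then again with an estimated correlation. Class shares were compared by a two-sided exact permutation of genotype within each assay over 400 relabellings, whose smallest p is 0.005. Comparisons of a single gene in 3 against 3 libraries used a two-sided exact permutation test, which cannot go below 0.1.

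Genes were named by a rule: Serpina3n in every library; in a fibroblast comparison up to 10 genes per direction, and in another class up to 5, with the largest fold among those past the threshold whose CKO libraries all lay on one side of the WT libraries, leaving out predicted, mitochondrial and ribosomal protein genes; from each list with a call, the 4 members with the smallest p; and, where a comparison had no call, the 5 genes with the smallest p. In classes other than fibroblasts the lists described were chosen from those called, after their values were seen, and the counts cover all. List members so named that passed adjusted over the list alone are all given, and most of those that did not pass are left out, a member of the complement list among them. CPM are UMI counts of a gene per 1000000 UMIs of its class and library, without TMM scaling unless a fitted fold change is given. Alternatives were DESeq2, RLE size factors, no filter and a stricter filter on low counts (mean of at least 10 CPM), called doublets kept, stricter barcode filters (1000 genes and 10% in cells, 500 and 2% in nuclei), equal numbers of barcodes per library, Leiden resolution 2, an estimated correlation, and leaving out each library in turn. After the data were seen, a fit with fibroblast-like unnamed clusters joined and one on nuclei with 1000 to 2500 UMIs were added. Shares of cells with a UMI were computed after thinning each cell to 5000 UMIs. On counts simulated from the real libraries with 200 changed genes, edgeR recovered 81 of 100 genes changed 2-fold and 99 of 100 changed 4-fold in fibroblast cells, 65 and 91 in fibroblast nuclei, and 34 and 67 for the interaction. Each gene was drawn on its own, at the spread fitted as a trend over genes. No structure of the samples beside assay and genotype was put in, so recovery in the real libraries can be lower. Replicate libraries differed by more than sampling noise, so none was counted as a copy (chi-square per degree of freedom 23.2 to 197). Sums over different cells exceed that noise whatever their origin, so this does not show that libraries with a shared title number come from separate samples.

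The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.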

Results

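Hearts of wild-type (WT) mice and of mice with a conditional knockout (CKO) of Serpina3n were profiled 7 days after myocardial infarction, as single cells and as single nuclei, with 3 libraries in each of the 4 groups. Cells libraries held 110832436 to 127830138 UMIs over 9694 to 13911 barcodes, and nuclei libraries 10912646 to 33269347 UMIs over 5154 to 12709 barcodes. After filtering, 50870 cells and 50127 nuclei were kept. The median depth of kept barcodes parted the genotypes in both assays: 7744 to 10627.5 UMIs in WT and 11256 to 13245 in CKO cells libraries, but 1572 to 1821 in WT and 1094.5 to 1264 in CKO nuclei libraries. The cells divided into 21423 macrophages, 15471 fibroblasts, 4145 endothelial cells, 674 mural cells, 479 cardiomyocytes and smaller classes, and the nuclei into 12275 endothelial, 12088 cardiomyocyte, 12048 fibroblast and 6349 macrophage nuclei and smaller classes. The sample titles give the 3 WT cells libraries one shared number, the 3 WT nuclei libraries another, and CKO cells replicates 1 and 2 yet another, without saying what these stand for. CKO cells replicate 3 and the 3 CKO nuclei libraries each have their own.

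The first question was whether Serpina3n, which codes for a secreted inhibitor of serine proteases, was lower in CKO hearts and in which cells. In the cells libraries its RNA was found in fibroblasts, the cells that lay down the scar, and in smaller classes too, and in fibroblasts it was lower in all 3 CKO libraries. It stood at 712, 671 and 889 CPM in WT replicates 1 to 3 and at 287, 271 and 375 CPM in CKO replicates 1 to 3, with means of 757 ± 116 and 311 ± 55.8 CPM (SD, n = 3 each), so that 41.1% of the WT level was left. Mural cells, the pericytes and smooth muscle of vessels, held 237 ± 59.6 CPM in WT and 135 ± 58.4 in CKO. Lymphatic endothelial cells held 719, 313 and 431 CPM in WT replicates 1 to 3 and 88.8, 203 and 219 CPM in CKO, from 38 to 63 cells per library. Epicardial cells, of the outer layer of the heart, held 108, 121 and 107 CPM in WT and 36.7, 29.1 and 36.9 CPM in CKO, from 19 to 276 cells. Endothelial cells stood at 8.82 CPM in WT and 4.98 in CKO, and macrophages at 6.0 and 3.41; RNA carried over from other droplets can reach such levels, and its share was not estimated. The fibroblast values rest on 103156 UMIs in WT and 41230 in CKO, and the groups did not overlap (two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries can give). The fitted log2 fold change was −1.21 (SE 0.17, 95% interval −1.59 to −0.82), with an adjusted p of 0.135 in edgeR's quasi-likelihood test over all genes, which did not pass 0.05. It passed without CKO cells replicate 3 (log2 −1.36, edgeR adjusted p = 0.0261). The CKO libraries then left share a title number, as do the WT ones, so the spread within groups may be partly technical. Within each of the 5 fibroblast clusters the log2 fold change lay between −1.49 and −1.06. With every cell thinned to 5000 UMIs, 76.9% ± 3.65 of WT and 48.5% ± 4.06 of CKO fibroblasts had a Serpina3n UMI (90.6% and 69.0% before thinning), against 2.68% and 1.73% of macrophages. Shallower cells, 375 WT and 175 CKO fibroblasts, were left out of the thinned shares, and library medians were 14298 to 19859 UMIs in fibroblasts and 9775 to 11919.5 in macrophages.

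Fibroblast nuclei held far less Serpina3n RNA, and it was not lower in the nuclei libraries labelled CKO. The 3 WT nuclei libraries held 21.7, 50.3 and 27.0 CPM and the 3 labelled CKO 84.7, 21.2 and 30.6 CPM, means of 33.0 ± 15.2 and 45.5 ± 34.3, from 475 and 324 UMIs. The fitted log2 fold change was 0.74 (SE 0.37, 95% interval −0.05 to 1.53; edgeR adjusted p = 0.523), and 0.03 without CKO nuclei replicate 1. Because this goes against the labels, the nuclei groups are named below only by their labels. The gene (ENSMUSG00000021091) lies on chromosome 12 at 104406729 to 104414329 of GRCm38, on the forward strand, in 5 exons. A 3' kit reads mostly the end of the transcript, here the 3' UTR at 104413604 to 104414329 in exon 5; where the deleted part does not include it, such tags do not check the deletion, and the deleted part is not given in the sources used here. The paralogs Serpina3f, Serpina3g, Serpina3i, Serpina3j, Serpina3k and Serpina3m lie nearby and could share tags with it.

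**Figure D1:**
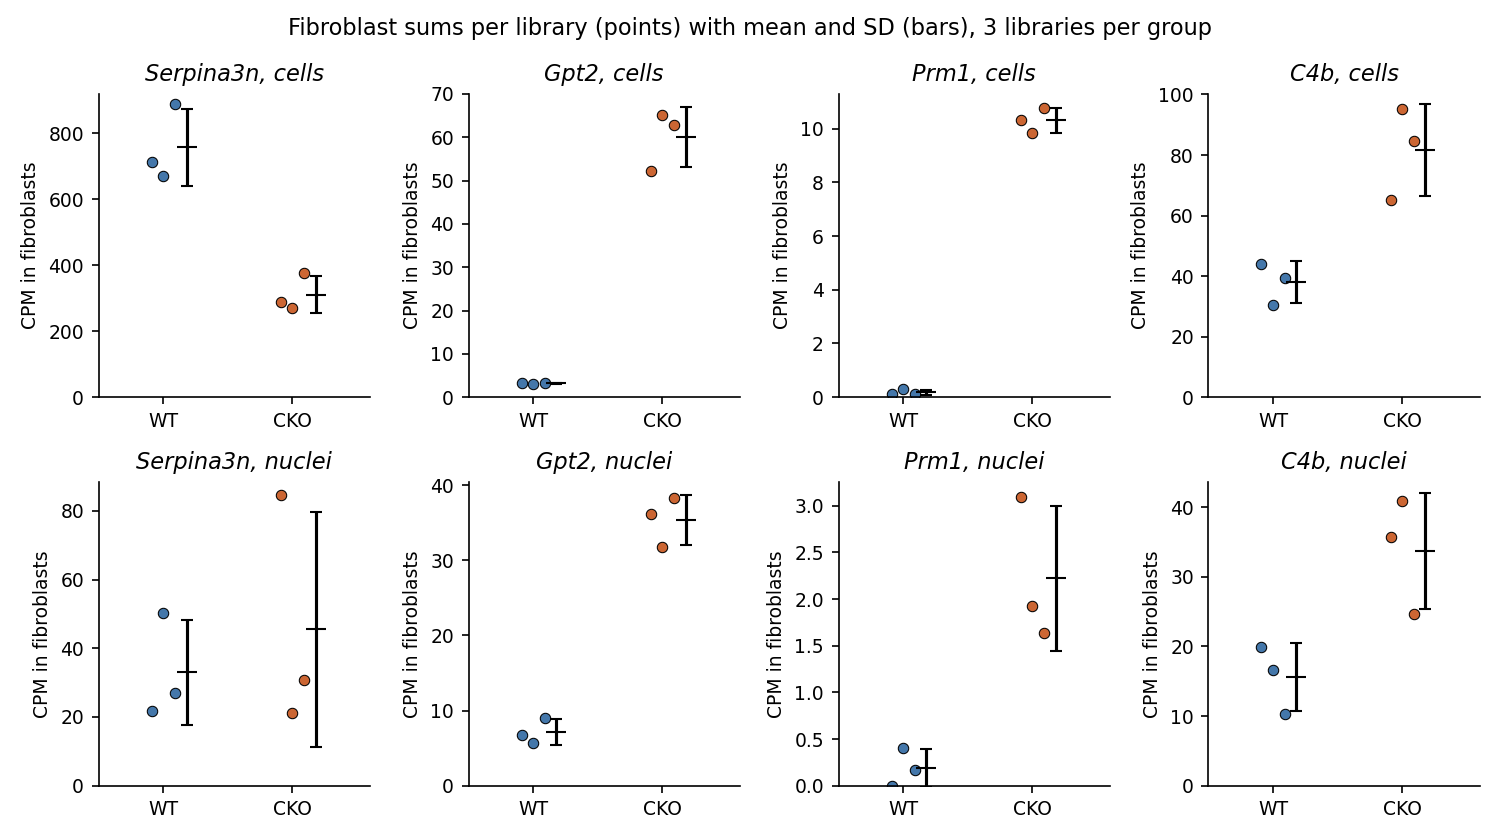
CPM of Serpina3n, Gpt2, Prm1 and C4b in fibroblasts of each library, cells in the upper and nuclei in the lower row. Points are libraries and bars the mean and SD of 3. The C4b values are scaled by TMM over both assays, and those of the other genes are not scaled. Serpina3n is lower in CKO cells (311 against 757 CPM) but not in the nuclei labelled CKO, while Gpt2 is higher in both.

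Of the classes tested, which leave out mural cells, fibroblasts had the single genes that passed, and all of these were higher in CKO. In the cells libraries these were Gpt2, Prm1 and Id1. Gpt2 codes for a mitochondrial alanine aminotransferase, and rose from 3.09 ± 0.18 to 61.7 ± 6.75 CPM (scaled by TMM; log2 4.32, SE 0.11, edgeR adjusted p = 5.85e-06). Prm1, a protamine that packs sperm DNA and is otherwise a gene of the testis, rose from 0.17 to 10.6 CPM (log2 5.98, SE 0.27, edgeR adjusted p = 0.000172), resting on 23 UMIs in WT and 1369 in CKO. Id1, an inhibitor of basic helix-loop-helix transcription factors and a target of BMP signalling, rose from 66.9 ± 7.42 to 154.3 ± 9.94 CPM (log2 1.21, SE 0.10, edgeR adjusted p = 0.0142). All 3 genes were higher in each CKO library than in any WT library. Of 14669 genes tested with edgeR, 3 were higher and 0 lower; 1776 had an unadjusted p under 0.05, 707 of them lower, and DESeq2 called 269 genes higher and 66 lower. The libraries of the 2 genotypes did not overlap for 17.8% of genes, against 10% by chance. The count of calls was 6 without WT replicate 1 and 109 without CKO replicate 3, the one cells library with high Y-linked RNA. Without CKO replicate 3, the CKO libraries left share a title number, as do the WT ones. The spread within groups may then be partly technical. Id1 was not called without WT replicate 2, WT replicate 3, CKO replicate 1 or CKO replicate 2 (edgeR adjusted p = 0.059, 0.166, 0.13 and 0.108), nor with unnamed fibroblast-like clusters joined (0.0665). Gpt2 and Prm1 were called each time. The cluster with most WT fibroblasts was 23, led by Thbs4, Cilp and C1qtnf3 (30.8% of them), and that with most CKO fibroblasts was 10, led by Sfrp2, Wisp2 and Comp (46.5%, against 22.1% in WT).

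Gpt2 (ENSMUSG00000031700) lies on chromosome 8 at 85492576 to 85527560, forward strand, Prm1 (ENSMUSG00000022501) on chromosome 16 at 10796326 to 10805839, reverse strand, and Id1 on chromosome 2 at 152736251 to 152737410, forward strand. None lies on the chromosome of Serpina3n. Gm46563 and Gm10343 overlap Prm1 on the other strand. Both Gpt2 and Prm1 were also high in CKO mural cells: Prm1 stood at 0 UMIs in WT and 50 in CKO, and Gpt2 at 1.15 and 49.8 CPM. Macrophages held 0.116 and 0.194 CPM of Prm1 and 6.10 and 9.56 CPM of Gpt2 in WT and CKO. With cells thinned to 5000 UMIs, 1.35% of WT and 24.2% of CKO fibroblasts had a Gpt2 UMI, against 2.44% and 4.36% of macrophages.

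Among the gene lists in fibroblast cells, those of acute inflammation lay mostly above 0 in CKO and those of genes induced by interferon below. Of 12 tested genes of the acute phase and of STAT3 signalling, which act downstream of interleukin-6, 4 rose when adjusted over the list alone: Cebpd (log2 0.73), Cebpb (0.89), Socs3 (0.61) and Osmr (0.33). Among 23 chemokines and inflammatory cytokines, 6 rose adjusted over the list alone, with Il6 at log2 1.73 (SE 0.24), the neutrophil attractants Cxcl1 at 1.14 and Cxcl2 at 1.29, and the adhesion molecule Icam1 at 0.90. Complement genes, of the cascade that tags debris and microbes, lay above 0 in 14 of 15 cases, and C4b (log2 1.11) rose adjusted over the list alone; C1ra and Cfb, which did not, had 0.37 and 0.61. All 21 interferon response genes lay below 0, and 14 fell adjusted over the list alone, among them the antiviral genes Ifit3 (log2 −1.09), Mx1 (−1.35), Xaf1 (−0.81) and Rsad2 (−1.31). No member of these lists passed edgeR's test adjusted over all genes tested; DESeq2 called Il6, Cebpd, C4b and Ifit3, among others. In the camera test the acute phase list was higher (median log2 0.38, adjusted p = 3.35e-05), as were the chemokine list (0.29, adjusted p = 0.00011) and the complement list (0.28, adjusted p = 0.000255), and the interferon list was lower (−0.69, adjusted p = 1.28e-21). These calls did not hold when the correlation was estimated from the libraries (adjusted p = 0.441 with an estimated correlation for the acute phase, chemokine and interferon lists, and 0.448 for complement). The interferon genes together stood at 2319, 2434 and 2011 CPM in WT replicates 1 to 3 and at 1264, 1183 and 1982 in CKO replicates 1 to 3. The immediate early and heat shock genes that respond to tissue dissociation moved with these lists: 17 of 20 lay above 0 and 8 rose adjusted over the list alone, among them Ier3 (log2 0.88), Dusp1 (0.45) and Junb (0.43), with a median of 0.33 (camera adjusted p = 6.12e-09, and adjusted p = 0.448 with an estimated correlation).

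Among the lists of scar, cartilage, contractile and cell cycle genes, few members passed in CKO fibroblasts. Of 10 late scar genes, 3 rose adjusted over the list alone: the Wnt inhibitor Sfrp2 (log2 1.05), the matrix protein Comp (1.01) and the cartilage protein Chad (1.52); Fmod, which did not, had 0.41, and 5 of the 10 lay below 0. Sfrp2 and Comp lead cluster 10, so these values can follow the larger part of CKO fibroblasts in it; the list was not tested within clusters. Comp and Chad also belong to the cartilage and bone list, in which Acan (0.86) rose and Spp1 (−0.78) fell adjusted over the list alone. All 14 contractile genes of myofibroblasts lay below 0 and 18 of 23 proliferation genes did, though none passed adjusted over the list alone. Among targets and ligands of TGF-beta, the main cytokine of scarring, Tgfb2 (log2 0.62), the feedback inhibitors Smad7 (0.85) and Skil (0.48), and Bambi (0.52) rose adjusted over the list alone, 4 of 12. Of 12 cathepsins, lysosomal proteases, Ctsf (0.66) and Ctsl (0.42) rose adjusted over the list alone, and 1 of 11 Wnt pathway genes did. No member passed edgeR's test adjusted over all genes tested; DESeq2 called Sfrp2, Comp, Smad7 and Tgfb2, among others. By camera the lists were higher for late scar (median log2 0.19, but −0.037 with the stricter count filter; adjusted p = 0.000808), TGF-beta (0.16, adjusted p = 0.00148), cathepsins (0.18, adjusted p = 0.00291), mitochondrially encoded genes (0.24, adjusted p = 0.00291), cartilage and bone (0.33, adjusted p = 0.029) and the Wnt pathway (0.17, adjusted p = 0.0426), and lower for proliferation (−0.34, adjusted p = 0.00292) and contractile genes (−0.28, adjusted p = 0.0221). None held with an estimated correlation (adjusted p = 0.441 with an estimated correlation for late scar, cathepsins, cartilage and bone, and Wnt, 0.479 for TGF-beta, 0.448 for mitochondrial genes, and 0.751 for proliferation and contractile genes). Collagen genes had a median of −0.12 (camera adjusted p = 0.63) and other serine protease inhibitors 0.04 (camera adjusted p = 0.547).

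Markers of other cell types moved in the same fibroblast sums: 9 endothelial markers had a median log2 of −0.82 (camera adjusted p = 0.00244, and adjusted p = 0.556 with an estimated correlation), Egfl7 (−0.82) and Fabp4 (−1.27) falling adjusted over the list alone, and 8 cardiomyocyte markers −0.61 (camera adjusted p = 0.0221, and adjusted p = 0.582 with an estimated correlation). Macrophage markers had a median of 0.23 (camera adjusted p = 0.172) and fibroblast markers 0.03. In all, 15 of 39 lists passed the preset correlation in fibroblast cells, 10 higher and 5 lower, and 0 passed with an estimated one, where 1 had an unadjusted p under 0.05. Without WT replicate 1, the endothelial, cardiomyocyte, cartilage and bone, cathepsin and Wnt lists were not called (camera adjusted p = 0.055, 0.148, 0.142, 0.142 and 0.0889). Without WT replicate 2 the contractile list was not (0.397), and without WT replicate 3 the contractile, cartilage and bone, and Wnt lists were not (0.187, 0.0636 and 0.113). The Wnt list was not called without CKO replicate 1 (0.1), the contractile list without CKO replicate 2 (0.502), nor the endothelial and cardiomyocyte lists without CKO replicate 3 (0.0525 and 0.239).

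**Figure D2:**
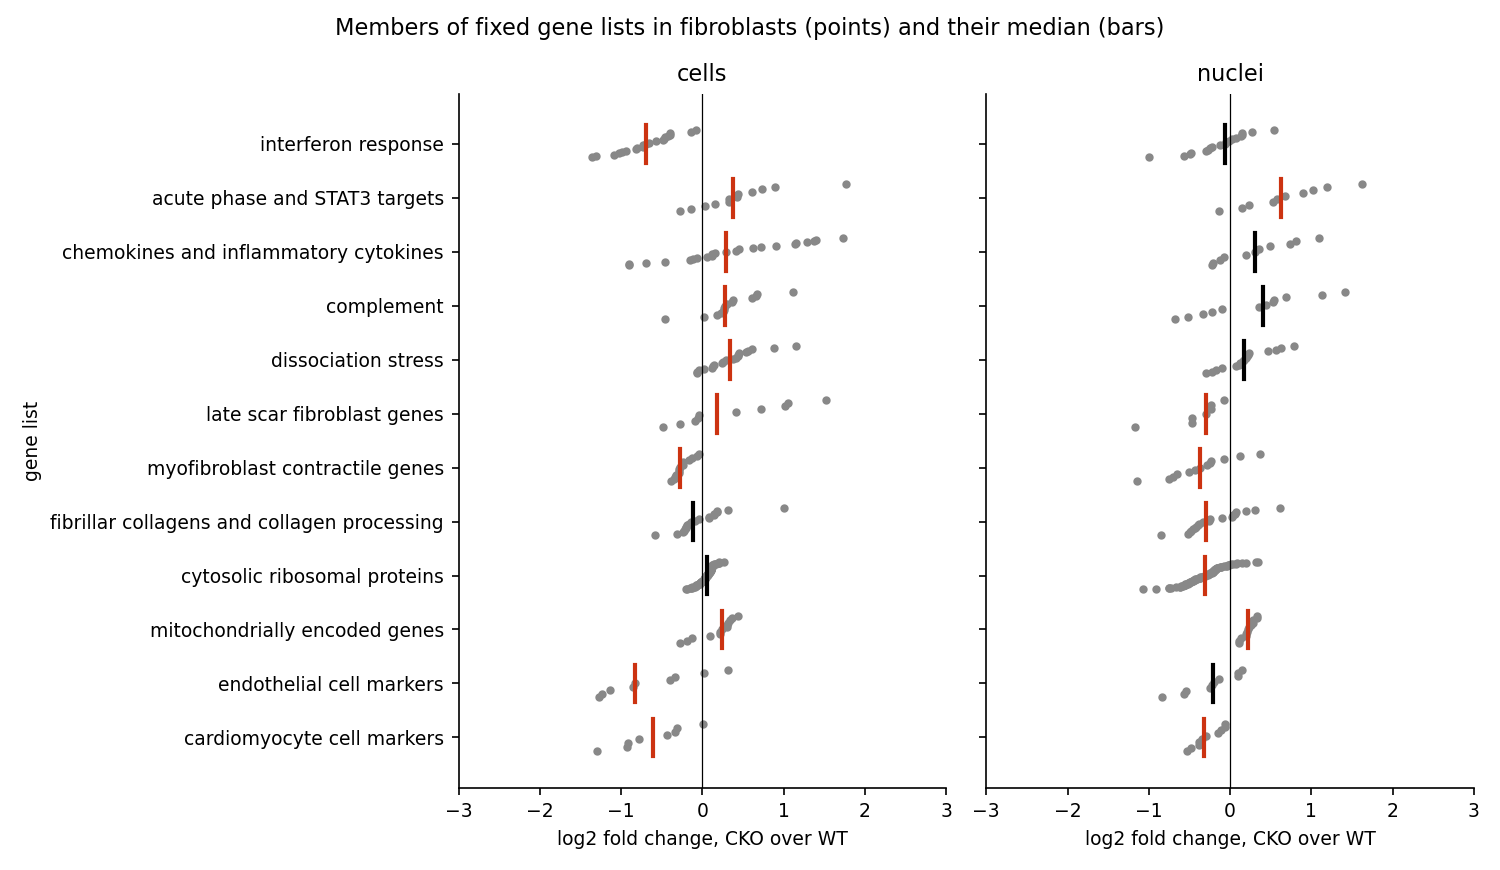
Log2 fold changes (CKO over WT) of the members of 12 gene lists in fibroblasts, in cells and in nuclei; points are genes and bars the list medians, red where the camera test with a preset correlation had an adjusted p under 0.05. All 21 interferon genes lie below 0 in cells (median −0.69), whereas their median is −0.07 in nuclei.

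Fibroblasts were also compared as nuclei, which need no enzymatic release of cells. Gpt2 was again higher in the libraries labelled CKO, with 5 further genes. Gpt2 rose by a log2 of 2.54 (SE 0.24, edgeR adjusted p = 0.000498), from 7.16 ± 1.71 to 35.4 ± 3.34 CPM without TMM scaling. Cd302, a C-type lectin receptor, rose by 1.19 (SE 0.15, edgeR adjusted p = 0.00934). Cntfr, the receptor of ciliary neurotrophic factor, an interleukin-6 family cytokine, rose by 1.19 (SE 0.19), Enc1, an actin-binding protein, by 1.23 (SE 0.20), Podn, a small leucine-rich proteoglycan of the matrix, by 1.13 (SE 0.18), and Errfi1, a feedback inhibitor of the EGF receptor, by 1.09 (SE 0.17), all with an edgeR adjusted p of 0.0407. Prm1 stood at 3 UMIs in WT and 14 in the libraries labelled CKO and was not tested. Of 12132 genes, 6 were higher and 0 lower by edgeR, 1241 had an unadjusted p under 0.05, and DESeq2 called 48 higher and 3 lower. The count was 1 without WT replicate 2 or WT replicate 3, 3 without CKO replicate 2, 9 without CKO replicate 1 and 17 without CKO replicate 3. Gpt2 was called each time; Cd302 was not without WT replicate 2 (edgeR adjusted p = 0.138) or WT replicate 3 (0.0524), and Errfi1 was not without any 1 of the 6 libraries (0.0524 to 0.275). Enc1 was called only without CKO replicate 1, and Cntfr and Podn only without CKO replicate 3; without the others their edgeR adjusted p was 0.0787 to 0.218 for Enc1, 0.0868 to 0.218 for Cntfr and 0.0647 to 0.218 for Podn. The libraries labelled CKO were the shallower ones (1094.5 to 1264 against 1572 to 1821 UMIs per nucleus). Podn overlaps Scp2 on the same strand, so tags of the pair may not be told apart.

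In fibroblast nuclei 11 of 38 lists were called by camera, 3 higher and 8 lower in the libraries labelled CKO. Acute phase genes were again higher, 6 of 10 rising adjusted over the list alone, among them the interleukin-4 receptor Il4ra (log2 1.02), haptoglobin (Hp, 1.62), Cebpb (0.68) and Steap4 (0.90). Of 12 genes of the unfolded protein response, which adjusts protein folding in the endoplasmic reticulum, Hspa5 (0.76) rose adjusted over the list alone. Among matrix and contractile genes few passed: 1 of 20 collagen genes fell adjusted over the list alone (P4ha3, −0.85), with Col1a1 at −0.50, Col1a2 at −0.44 and Serpinh1 at −0.52, and 1 of 13 contractile genes did (Tagln, −1.14), with Cnn2 at −0.65 and Acta2 at −0.71. All 7 late scar genes and 8 of 9 Wnt genes lay below 0. Of genes of other cells, Apoe (−0.80) among 11 lipid-associated macrophage genes and Xirp2 (−0.94) among 11 fetal cardiomyocyte genes fell adjusted over the list alone, all 10 cardiomyocyte markers lay below 0, and 74 of 82 ribosomal protein genes did. No member passed edgeR's test adjusted over all genes tested, though Xirp2, Il4ra and Tagln did with no filter on low counts. By camera the acute phase (median log2 0.63, adjusted p = 0.00035), unfolded protein (0.33, adjusted p = 0.00765) and mitochondrially encoded (0.22, adjusted p = 0.0165) lists were higher. The lists of ribosomal proteins (−0.30, adjusted p = 5.04e-09), collagens (−0.29, adjusted p = 0.00292), contractile genes (−0.37, adjusted p = 0.00292), fetal cardiomyocyte genes (−0.45, adjusted p = 0.00395), lipid-associated genes (−0.60, adjusted p = 0.00395), cardiomyocyte markers (−0.32, adjusted p = 0.00765), late scar (−0.30, adjusted p = 0.0199) and Wnt (−0.33, adjusted p = 0.0439) were lower. None of the 11 held with an estimated correlation (adjusted p = 0.588 with an estimated correlation for mitochondrial genes and 0.483 for the rest). The interferon (−0.07, adjusted p = 0.528), complement (0.40, adjusted p = 0.0768), chemokine (0.31, adjusted p = 0.107) and stress lists (0.18, adjusted p = 0.176) did not pass camera in nuclei. Without CKO replicate 1, 5 lists were called; the acute phase median was 0.27 (camera adjusted p = 0.367), and the collagen, contractile, late scar, Wnt and lipid-associated lists were not called (0.213, 0.213, 0.174, 0.174 and 0.0669). Without WT replicate 3, 7 were called, but not the lipid-associated, unfolded protein, Wnt and mitochondrial lists (0.116, 0.116, 0.116 and 0.118). Without WT replicate 1, 17 were called, but not late scar (0.243). Without WT replicate 2 the fetal cardiomyocyte, cardiomyocyte marker and mitochondrial lists were not called (0.107, 0.218 and 0.266), nor were cardiomyocyte markers without CKO replicate 2 (0.0767) or the late scar, Wnt and mitochondrial lists without CKO replicate 3 (0.0971, 0.103 and 0.286). The mitochondrial median turned to −0.070 with the stricter barcode filter. Nuclei cluster 14, led by Ltbp2, Klhl29 and Mfap4, held 45.9% of WT fibroblast nuclei and 31.3% of those labelled CKO. Cluster 15, led by Hmcn2, Tnxb and Lvrn, held 54.1% and 68.7%. The gene and list values of fibroblast nuclei can follow this mix.

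Cells and nuclei were then fitted together, with the assay as a term, for genes that differed over both. Gpt2 and Prm1 were joined by C4b, a complement component, by Myc, a transcription factor of growth, by Trib1, a scaffold for protein degradation, by Cebpb, a transcription factor of acute inflammation, and by Arhgap24, a GTPase-activating protein. In CPM scaled by TMM, C4b stood at 37.96 ± 6.91 in WT and 81.7 ± 15.3 in CKO cells and at 15.6 ± 4.85 and 33.7 ± 8.30 in nuclei (log2 1.12, SE 0.16, edgeR adjusted p = 0.0076). Myc rose by 1.06 (SE 0.12, edgeR adjusted p = 0.000975), Trib1 by 0.96 (SE 0.15, edgeR adjusted p = 0.0192), Cebpb by 0.81 (SE 0.14, edgeR adjusted p = 0.0458) and Arhgap24 by 0.67 (SE 0.12, edgeR adjusted p = 0.0458). Of 15903 genes 9 were higher and 0 lower by edgeR; 1449 had an unadjusted p under 0.05, and DESeq2 called 105. The other two, Nfil3 and Csrnp1, overlapped between genotypes in nuclei. Serpina3n had a log2 of −0.39 (SE 0.35, edgeR adjusted p = 0.784) over both assays. C4b lies on chromosome 17 at 34728380 to 34743882, and has a near-identical copy, C4a, that could share its tags. Prm1, Gpt2, C4b and Myc were called without each library in turn; Trib1 was not without cells WT replicate 2 (0.0842), cells WT replicate 3 (0.0709), cells CKO replicate 1 (0.0685) or cells CKO replicate 2 (0.0769). Cebpb was called only without cells CKO replicate 3 or nuclei CKO replicate 3, and Arhgap24 only without cells WT replicate 1, cells CKO replicate 3 or nuclei CKO replicate 2; without the other libraries their edgeR adjusted p was 0.0513 to 0.169 and 0.0634 to 0.128. The count was 16 without cells WT replicate 1, 40 without cells CKO replicate 3, 17 without nuclei CKO replicate 2, 14 without nuclei CKO replicate 3, and 4 without cells WT replicate 2 or cells CKO replicate 2.

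Whether the genotype difference itself differed between cells and nuclei was asked by the interaction of assay and genotype in fibroblasts. Gpt2 was the 1 gene of 16391 called: its rise was smaller in nuclei, by a log2 of −1.78 (SE 0.25, edgeR adjusted p = 0.0428). Serpina3n had an interaction of 1.96 (SE 0.48, edgeR adjusted p = 0.242), and 1647 genes had an unadjusted p under 0.05; DESeq2 called 136. Gpt2 was called without cells CKO replicate 1, cells CKO replicate 3, nuclei WT replicate 2 or nuclei CKO replicate 3, and the count was 3 without cells CKO replicate 3 or nuclei CKO replicate 3; without any of the other 8 libraries 0 genes were called (Gpt2 at an edgeR adjusted p of 0.068 to 0.275).

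Macrophages, which clear debris and direct repair, held no called gene, but their lists moved. In the cells libraries all 21 interferon genes lay below 0 in CKO macrophages and 5 fell adjusted over the list alone, among them Rsad2 (log2 −1.34), Ifit1 (−1.59), Cmpk2 (−1.48) and Xaf1 (−0.84). TGF-beta genes lay above 0 in 11 of 12 cases, with Smad7 (0.58) and Tgfb2 (1.23) rising adjusted over the list alone, and complement genes in 13 of 14. By camera the interferon list was lower (median log2 −0.82, adjusted p = 5.04e-21) and the TGF-beta (0.38, adjusted p = 3.31e-06) and complement (0.33, adjusted p = 0.000441) lists higher. None of the 3 held (adjusted p = 0.556 with an estimated correlation for each). Markers of other cells moved beside them: 4 of 8 neutrophil markers rose adjusted over the list alone, with S100a8 at 2.88 and S100a9 at 3.79 (median 0.74, camera adjusted p = 8.29e-06), endothelial markers were lower (−0.92, camera adjusted p = 3.98e-11; Cdh5 −1.57 and Kdr −1.32), and cardiomyocyte markers were lower (−0.98, camera adjusted p = 0.000721). None of these markers held either (adjusted p = 0.772 with an estimated correlation for cardiomyocytes and 0.556 for the others), and cardiomyocyte markers were not called without WT replicate 1 (camera adjusted p = 0.0906) or CKO replicate 3 (0.139). In all, camera called 7 of 39 lists higher and 5 lower in these macrophages, and 0 with an estimated correlation (lowest adjusted p = 0.556 with an estimated correlation). No member passed edgeR's test over all genes. Of 13325 genes edgeR called 0; 1204 had an unadjusted p under 0.05, and DESeq2 called 87. The 5 smallest p belonged to Gm26802 (log2 −1.71), the B cell attractant Cxcl13 (1.00, SE 0.12), Rbp7, a gene of endothelial cells (−4.23), Gm20186 (0.86) and Slc25a22 (−0.59), with edgeR adjusted p of 0.431 to 0.496; Serpina3n had −0.72 (edgeR adjusted p = 0.496). Without CKO cells replicate 3, which alone held high Y-linked RNA, 326 genes were called. The CKO libraries left in that fit share a title number, as do the WT ones, so the spread within groups may be partly technical. The cluster with most WT macrophages was 12, led by Fcrls, Ccl8 and Ms4a7 (23.2%, against 16.6% in CKO), and that with most CKO macrophages was 3, led by Ms4a7, C1qc and Gpnmb (21.02%, against 12.5% in WT). The macrophage values can follow this mix.

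In macrophage nuclei some genes of resident macrophages, the long-lived macrophages of the heart, were higher in the libraries labelled CKO. Lyve1 (log2 1.29), Mrc1 (1.05) and Cd163 (0.91) rose and Igf1 (−0.65) fell adjusted over the list of 10 resident genes alone. Of 12 lipid-associated genes 11 lay below 0, with Fabp5 at −1.14, Lgals3 at −0.89 and Trem2 at −0.72, none of which passed adjusted over the list alone. By camera the resident list was higher (median 0.51, adjusted p = 0.000796) and the lipid-associated list lower (−0.43, adjusted p = 0.00265), as were fibroblast markers (−0.59, adjusted p = 0.00063) and ribosomal proteins (−0.42, adjusted p = 3.66e-09); none held (adjusted p = 0.474 with an estimated correlation for each). The lipid-associated list was not called without WT replicate 2 (camera adjusted p = 0.0504), nor the fibroblast markers without WT replicate 3 (0.0641). In all, camera called 3 of 35 lists higher and 9 lower, and 0 with an estimated correlation (lowest adjusted p = 0.474 with an estimated correlation), with no member past edgeR's test over all genes. Nuclei cluster 6, led by Mrc1, F13a1 and Adgre1, held 68.4% of WT macrophage nuclei and 89.9% of those labelled CKO. Cluster 7, led by Cd84, Gpnmb and St18, held 31.6% and 10.1%. The values above can follow this mix. Of 9703 genes edgeR called 0, 972 had an unadjusted p under 0.05, and DESeq2 called 39; 8 were called without WT replicate 1. The smallest p belonged to the flagellin receptor Tlr5 (log2 1.40, edgeR adjusted p = 0.0935), Ms4a4a (1.32, edgeR adjusted p = 0.151), Syne2 (1.07), Lyve1 (1.29) and Ucp2 (0.96).

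In endothelial cells, the lining of vessels, interferon genes also lay mostly below 0 in the CKO cells libraries, and 4 complement genes were higher. Of 20 interferon genes 19 lay below 0 and 8 fell adjusted over the list alone, among them Xaf1 (log2 −0.75), Oas1a (−1.05), Ifit2 (−1.23) and Ifit3 (−1.24). Of 11 complement genes 4 rose adjusted over the list alone: C4b (1.34), C1ra (1.13), and C1qb (0.70) and C1qc (0.55), which are macrophage genes; the 9 macrophage markers had a median of 0.46, 8 of them above 0 (camera adjusted p = 0.00329, and adjusted p = 0.419 with an estimated correlation). The dissociation stress genes lay above 0 in 16 of 20 cases, Nr4a1 (1.05) rising adjusted over the list alone, and all 5 cardiomyocyte markers lay below 0. By camera the interferon list was lower (median −0.55, adjusted p = 6.84e-16), the complement list higher (0.58, adjusted p = 5.78e-06), the stress list higher (0.29, adjusted p = 5.98e-06) and the cardiomyocyte markers lower (−1.46, adjusted p = 0.042). None held with an estimated correlation (adjusted p = 0.377 with an estimated correlation for interferon and complement, 0.419 for stress and 0.53 for cardiomyocyte markers). The complement list was not called with called doublets kept (camera adjusted p = 0.489) or with finer clustering (0.914, median −0.39), and with these the macrophage markers turned to medians of −0.43 and −0.81; without CKO replicate 2 the markers were not called (camera adjusted p = 0.345), nor was the stress list without WT replicate 2 (0.0598) or the cardiomyocyte markers without CKO replicate 2 (0.0552) or CKO replicate 3 (0.243). In all, camera called 20 of 35 lists higher and 2 lower, and 0 with an estimated correlation (lowest adjusted p = 0.377 with an estimated correlation), with no member past edgeR's test over all genes. Cells cluster 0, led by Fabp4, Gpihbp1 and Cdh5, held 42.9% ± 28.9 of WT and 13.9% ± 8.66 of CKO endothelial cells. Cluster 1, led by Cdh5, Fabp4 and Egfl7, held 54.2% and 80.9%. This mix can set the values above. Of 10775 genes edgeR called 0, 1011 had an unadjusted p under 0.05, and DESeq2 called 48; 3 were called without WT replicate 2. The smallest p belonged to Il6 (log2 1.06), Sulf1 (0.98), Gm17056 (1.37), Srarp (−4.51) and Nuak1 (0.90), each with an edgeR adjusted p of 0.311, and Serpina3n had −0.73 (edgeR adjusted p = 0.509).

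In endothelial nuclei the adhesion molecules Vcam1 (log2 0.88) and Icam1 (0.54), which hold leukocytes on the vessel wall, and the alarm cytokine Il33 (0.95) rose adjusted over the list of 9 chemokine and cytokine genes alone, in the libraries labelled CKO. That list was higher by camera (median 0.42, adjusted p = 0.00189, and adjusted p = 0.655 with an estimated correlation), but not without CKO replicate 1 (adjusted p = 0.0569). Fibroblast markers (−0.65, camera adjusted p = 0.00139) and ribosomal proteins (−0.36, camera adjusted p = 3.8e-13) were lower, each with adjusted p = 0.727 with an estimated correlation, and the fibroblast markers were not called without WT replicate 3 (camera adjusted p = 0.0612). In all, camera called 1 of 38 lists higher and 15 lower, and 0 with an estimated correlation (lowest adjusted p = 0.655 with an estimated correlation), with no member past edgeR's test over all genes. Nuclei cluster 1, led by Mcf2l, Ushbp1 and Btnl9, held 32.9% of WT endothelial nuclei and 18.1% of those labelled CKO. Cluster 9, led by Mcf2l, Btnl9 and Ushbp1, held 35.8% and 48.1%, and this mix can set the values above. Of 12457 genes edgeR called 0, 1408 had an unadjusted p under 0.05, and DESeq2 called 71; 8 were called without CKO replicate 1. The smallest p belonged to the imprinted gene Peg3 (log2 1.20) and Smpd3 (1.07), with an edgeR adjusted p of 0.158, Spock2 (1.20), Ahnak (1.04) and Gipc2 (−1.26). Serpina3n had 0.28 (edgeR adjusted p = 0.811), and −0.10 without CKO replicate 1.

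Cardiomyocytes, the muscle cells of the heart, were compared in nuclei, where 2 of 16 glycolysis and hypoxia genes were higher in the libraries labelled CKO. Pfkl and Hk2, enzymes of early glycolysis, both rose by a log2 of 0.87 adjusted over the list of 16 alone, and 12 of the 16 lay above 0 (median 0.23, camera adjusted p = 0.00908, and adjusted p = 0.564 with an estimated correlation); the list was not called without WT replicate 3 (camera adjusted p = 0.822) or CKO replicate 1 (0.168). Transcripts of other cells were lower in the same nuclei. All 9 fibroblast markers lay below 0, 8 of them past the test adjusted over the list alone (median −1.09, camera adjusted p = 1.74e-06), as did 19 of 20 collagen genes (−0.92, camera adjusted p = 1.22e-09) and all 10 endothelial markers (−0.60, camera adjusted p = 4.14e-06), and ribosomal proteins were lower too (−0.33, camera adjusted p = 7.76e-08); none held (adjusted p = 0.55 with an estimated correlation for each). In all, camera called 1 of 37 lists higher and 18 lower, and 0 with an estimated correlation (lowest adjusted p = 0.55 with an estimated correlation), with no member past edgeR's test over all genes. Nuclei cluster 17, led by Mhrt, Ttn and Coro6, held 4.62% of WT cardiomyocyte nuclei and 35.3% of those labelled CKO. Cluster 8, led by Coro6, Ttn and Xirp2, held 45.4% and 23.7%. The values above can follow from this mix too. Ribosomal proteins were also lower in fibroblast, macrophage and endothelial nuclei, and fibroblast markers in macrophage and endothelial nuclei. These falls are thus not particular to cardiomyocytes. The share of RNA carried over from other droplets was not estimated. Of 13053 genes edgeR called 0, 1347 had an unadjusted p under 0.05, and DESeq2 called 21. The smallest p belonged to Mvd, an enzyme of cholesterol synthesis (log2 2.27, edgeR adjusted p = 0.0539), Slc24a2 (−1.50), 1700113H08Rik (1.58), Astn2 (1.44) and Pcdhga1 (1.21), and Serpina3n had 0.74 (edgeR adjusted p = 0.649).

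The make-up of the tissue was compared by class shares over both assays. Live sorting, dissection and the depth gap between genotypes can each set such shares, as can the unnamed clusters, which held 26.3% of WT cells replicate 2. Unnamed cells cluster 8 held 19.4% of that library and 1.12% to 2.06% of the others. Unnamed cells cluster 25 held 0.372%, 0.407% and 0.787% of WT and 5.67%, 1.26% and 3.86% of CKO replicates 1 to 3. It was picked after the values were seen and was not tested. Endothelial cells made up 12.5% ± 9.51 of WT and 3.56% ± 0.361 of CKO cells, and 25.5% ± 3.06 and 23.3% ± 1.23 of nuclei (SD, n = 3 each). The mean difference over the assays was −5.59 percentage points (exact permutation p = 0.015, adjusted p = 0.105 over 7 classes). WT replicate 1 of the cells held 23.4%, and without it the difference was −2.87 points. Cardiomyocytes made up 20.99% ± 0.846 of WT nuclei and 29.95% ± 5.63 of those labelled CKO, but 1.25% ± 1.05 of WT and 0.624% ± 0.151 of CKO cells, with a mean difference over the assays of 4.17 points (exact permutation p = 0.08, adjusted p = 0.28). Fibroblasts made up 28.6% ± 8.18 and 33.1% ± 4.19 of cells and 24.3% ± 3.27 and 22.6% ± 2.71 of nuclei, and macrophages 39.0% ± 7.34 and 45.7% ± 5.48 of cells and 14.2% ± 0.452 and 9.74% ± 2.85 of nuclei (differences of 1.42 and 1.13 points, exact permutation with adjusted p = 0.985 for each). No class passed adjustment, and 1 of 7 had an unadjusted p under 0.05. With edgeR on numbers of barcodes per class no class passed either (lowest edgeR adjusted p = 0.218). It gave cardiomyocytes a log2 of −0.21 (SE 0.40) and macrophages −0.16 (SE 0.20), against the direction of their mean differences. Without one library in turn the fibroblast difference ranged from −0.91 to 2.91 points and the macrophage difference from −0.87 to 2.74, so neither has a set direction.

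**Figure D3:**
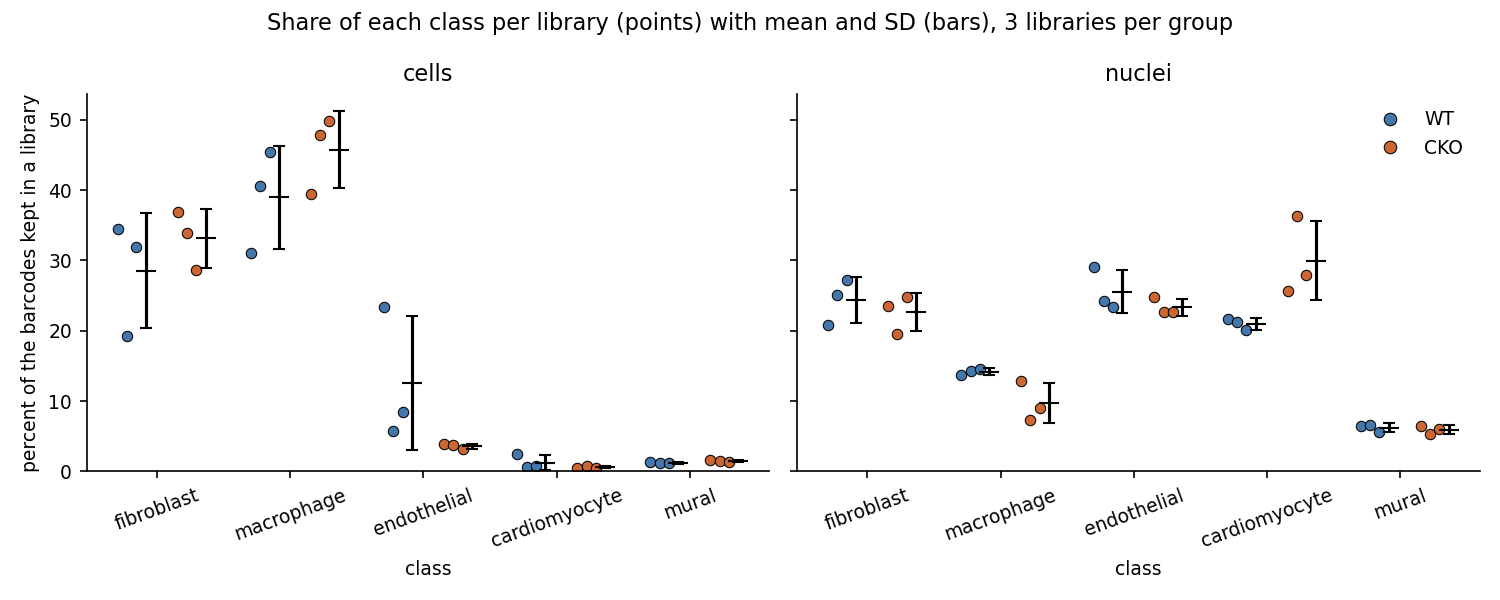
Percent of kept barcodes in each library that belong to 5 classes, in cells and in nuclei; points are libraries and bars the mean and SD of 3. WT endothelial cells range up to 23.4% in 1 library, against 3.56% on average in CKO.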

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

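Of the tests in this part, that on the proportions of fibroblast clusters was set before its result was seen, and the others, the counts over other splits of the libraries included, were chosen after.

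By the interaction of assay and genotype in fibroblasts, 1 gene was called between nuclei and cells, and lists differed only with a preset correlation. Gpt2 rose less in nuclei, by a log2 of −1.78. By camera with a preset correlation 10 of 44 lists differed, and 0 with an estimated one (adjusted p = 0.153 with an estimated correlation for the matricellular, late scar, cathepsin, Wnt and B cell lists, 0.589 for lipid-associated genes, 0.683 for collagens and interferon, 0.759 for macrophage markers and 0.797 for ribosomal proteins). With the preset one, matrix lists were lower in the nuclei comparison than in the cells comparison: collagens by a median log2 of −0.23 (camera adjusted p = 0.0364), with elastin (Eln) at −1.37, matricellular proteins by −0.24 (adjusted p = 0.00114), with Comp and Cthrc1 at −1.25, Bgn at −0.82 and Ccn5 at −0.93, and late scar genes by −0.56 (adjusted p = 0.00114), with Fmod at −1.59 and Sfrp2 at −1.51. The Wnt pathway (−0.49, camera adjusted p = 0.0224; Fzd2 −1.15), cathepsins (−0.42, adjusted p = 0.00816; Ctsl −0.78), ribosomal proteins (−0.37, adjusted p = 3.08e-09) and lipid-associated macrophage genes (−0.66, adjusted p = 0.000339; Apoe −1.46) went the same way. Markers of macrophages (−0.74, camera adjusted p = 0.00816) and of B cells (−1.74, adjusted p = 0.00336; Ighm −4.24, Bank1 −2.58) did too. The interferon list was the one that was higher (0.51, camera adjusted p = 1.76e-05; Stat2 0.74, Gbp3 1.26). The genes named here passed adjusted over the list alone, and Gpt2 alone passed over all genes tested. Over 19 alternatives the collagen list was not called in 9 and the macrophage markers were not in 8.

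Gpt2 and Prm1 stood far above WT in CKO fibroblasts, and in CKO mural cells. For Prm1, RNA carried over from other droplets is argued against by macrophages of the same libraries, which held at most 2.11% of its CPM in fibroblasts. Gpt2 stood at 6.10 CPM in WT and 9.56 in CKO macrophages, against 59.98 in CKO fibroblasts. Endothelial cells of the same CKO libraries held 1.99 ± 0.957 CPM of it, from 14 UMIs. This argues against carry-over as the source of the Gpt2 level in CKO fibroblasts. CKO cardiomyocytes held 19.7 ± 10.7 CPM, from 17 UMIs. A change spread over the region around Gpt2 is argued against by its 19 tested neighbours within 500 kb, with a median log2 of −0.019 (range −0.35 to 0.25), and a sperm programme by Prm2, Tnp1 and Tnp2, which had 0 UMIs in CKO fibroblasts and so lie under 0.219% of the Prm1 UMIs even at a floor of 3 counts. What stays open is the knockout itself, the Cre allele that comes with it, and a strain difference near either gene; the 3' end of Prm1 is used as a polyadenylation signal in some transgenes, so its tags may come from a construct, which UMI counts per gene cannot decide.

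Serpina3n was lower in CKO fibroblasts in cells (log2 −1.21) and not in nuclei (0.74), although the interaction did not pass (edgeR adjusted p = 0.242). Too few nuclear counts are argued against by the 95% interval in nuclei, whose lower bound of −0.053 lies above the value in cells, and the first CKO nuclei library alone by the lower bound of −0.76 that is left without it. Shallower nuclei in the libraries labelled CKO are argued against by nuclei with 1000 to 2500 UMIs alone, where the log2 was 0.83 (95% interval 0.051 to 1.61), and exchanged genotype labels by Gpt2, which in the lowest nuclei library labelled CKO was 3.51 times that of the highest WT library in fibroblasts. In macrophage nuclei (22.2 CPM in WT against 15.7) and cardiomyocyte nuclei (13.03 against 5.42) Gpt2 stood the other way, unlike in macrophages of the cells libraries (6.10 against 9.56), and mural nuclei (3.60 against 10.7) went with fibroblasts. A deletion that leaves unspliced nuclear RNA with its 3' end in place could give this pattern, but was not tested.

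By camera with a preset correlation the stress and acute phase lists were higher and the interferon list lower in CKO fibroblasts in cells, which did not hold otherwise (adjusted p = 0.448 with an estimated correlation for stress and 0.441 for the other lists). Other proportions of fibroblast clusters are argued against, since both held within 4 of the 5 clusters; cluster 21 had both lower (−0.19 and −0.25). The interferon list was also lower in macrophages (median −0.82, adjusted p = 0.556 with an estimated correlation) and endothelial cells (−0.55, adjusted p = 0.377 with an estimated correlation) of the same libraries, and so not in fibroblasts alone. It was not tested within the clusters of these classes. In mural cells Ifit3 stood at 26.0, 31.5 and 32.5 CPM in WT replicates 1 to 3 and at 6.95, 3.18 and 67.2 in CKO. Isg15 overlapped there too, but overlap between genotypes does not test a state of whole libraries. The mural Ifit3 values rest on 4 to 77 UMIs per CKO library. Ifit3 in CKO replicates 1 to 3 stood at 23.3, 21.8 and 35.8 CPM in fibroblasts and at 12.4, 9.86 and 42.0 in macrophages. Replicate 3 was thus the highest in these classes, as in mural cells. Isg15 in endothelial cells did not follow this order (173, 96.0 and 154). A state of whole libraries stays open. Handling of the tissue would raise the stress list in other classes too. Its median was 0.29 in endothelial cells and 0.12 in macrophages, where members went both ways. The labels give no batch, so handling cannot be told apart from genotype. An effect of the knockout on interferon signalling stays open too, with CKO replicate 3 close to WT in fibroblasts (1982 against 2011 to 2434 CPM), the one cells library with high Y-linked RNA and with a title number that no other shares.

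Other splits of the same libraries were fitted in the same way. The numbers of splits given here, and of those that reach a count, include the split by genotype itself. With 3 against 3 libraries the 10 splits are too few for a share under 0.05: 2 gave at least the 3 calls of fibroblast cells, with 137 in the highest other, and 2 gave at least the 6 of fibroblast nuclei, with 10 in the highest other. The same holds for the counts of 0 in other classes, which all 10 splits reach, with 341 in the highest other for macrophage cells, 33 for macrophage nuclei, 2 for endothelial cells, 10 for endothelial nuclei and 9 for cardiomyocyte nuclei. It holds for the 15 lists of fibroblast cells and the 11 of nuclei, which 3 of 10 splits reach each, with 19 and 14 in the highest other. For the combined fit 5 of 100 drawn splits reached the 9 calls (highest other 30), and for the interaction 8 of 100 reached the 1 call (highest other 35), so chance is excluded for neither count. The split with 137 and 341 calls set WT replicate 1 with CKO replicates 1 and 2 of the cells against the other 3, which points to a structure of the samples beside genotype. In nuclei the highest other split was the same each time, for the 10, 33, 10 and 9 calls and for the 14 lists. It set WT replicate 1 with CKO replicates 1 and 2, the libraries with Y-linked transcripts, against the other 3. This split was also the one beside genotype that reached the 6 calls of fibroblast nuclei. Sex-linked genes stayed in the tests, so its counts do not measure chance alone.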

How the results depend on the processing

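The fits with unnamed fibroblast-like clusters joined and on nuclei with 1000 to 2500 UMIs were chosen after seeing the data, and the other alternatives before, though not for the lists of classes other than fibroblasts. With the clusters joined 2 genes were called in fibroblast cells and Serpina3n had a log2 of −1.20. No paired analysis was possible because the replicate numbers are names in accession order and the labels pair no samples.

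Counts of called genes moved with the tool, the filter on low counts and the library left out; the cause was not tested. With DESeq2 they were 335 in fibroblast cells, 51 in fibroblast nuclei, 105 over both, 136 for the interaction, 87 in macrophage cells, 39 in macrophage nuclei, 48 in endothelial cells, 71 in endothelial nuclei and 21 in cardiomyocyte nuclei. With no filter, edgeR gave 27, 197, 151, 160, 1, 74, 164, 244 and 245 in the same order. The called fibroblast genes were called again under both. Serpina3n passed in fibroblast cells with DESeq2 (log2 −1.20, adjusted p = 4.89e-10) and with no filter (−1.21, edgeR adjusted p = 0.0255), and in fibroblast nuclei with no filter (0.72, edgeR adjusted p = 0.0465), in the other direction; over all alternatives its adjusted p ranged from 4.89e-10 to 0.613 in cells and from 0.0465 to 0.979 in nuclei. In fibroblast nuclei 2 genes were called with the stricter count filter, 1 with the stricter barcode filter, 3 with equal numbers of nuclei and 1 with finer clustering; over both assays 20 were called with the stricter barcode filter and 28 with equal numbers, and for the interaction 0 with equal numbers and 0 with finer clustering. In cardiomyocyte nuclei 1 gene was called with RLE size factors and 1 with equal numbers. With an estimated correlation 0 lists were called in fibroblast cells and 0 in nuclei. With the stricter barcode filter 1 class share passed, that of endothelial cells (exact permutation, adjusted p = 0.035; 0.035 to 0.35 over the alternatives).

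Leaving out 1 library gave 2 to 109 calls in fibroblast cells, 1 to 17 in fibroblast nuclei, 4 to 40 over both, 0 to 3 for the interaction, 0 to 326 in macrophage cells, 0 to 8 in macrophage nuclei, 0 to 3 in endothelial cells, 0 to 8 in endothelial nuclei and 0 in cardiomyocyte nuclei. It gave 12 to 17 lists in fibroblast cells and 5 to 17 in nuclei, and log2 values for Serpina3n of −1.36 to −1.05 in cells and 0.03 to 1.19 in nuclei.

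The following directions turned. In fibroblast nuclei mt-Nd2 went to −0.033 with the stricter barcode filter and to −0.14 with 1000 to 2500 UMIs, mt-Nd1 to −0.12 with the latter, and the mitochondrial list to −0.070 and −0.20. Macrophage markers in endothelial cells went to −0.43 with called doublets kept and to −0.81 with finer clustering, and the complement list there to −0.39 with the latter. The late scar list in fibroblast cells had a median of −0.037 with the stricter count filter, though camera still called it higher. Comp in fibroblast nuclei went to 0.030 with finer clustering and ranged from −0.44 to 0.015 without 1 library. Serpina3n in endothelial nuclei went to −0.27 with equal numbers and ranged from −0.10 to 0.52 without 1 library. The fibroblast share difference went to −0.51 points with the stricter barcode filter and −2.61 with finer clustering, and from −0.91 to 2.91 without 1 library. The macrophage share difference went to −0.36 with the stricter filter, and from −0.87 to 2.74. With edgeR on numbers of barcodes the cardiomyocyte and macrophage shares turned, to a log2 of −0.21 and −0.16. Of the other values of single genes and class shares, 909 without 1 library and 1103 under other settings kept their direction and their side of the threshold. Without 1 library 58 lost and 19 gained a call, and under other settings 29 lost and 88 gained one. Simulated 2-fold changes were recovered for 43 of 100 genes in macrophage and cardiomyocyte nuclei and 79 of 100 in macrophage cells; what limits them was not tested.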

Other observations

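All tests in this part were run after the values were seen.

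Mural cells, which wrap vessels, held inflammatory transcripts in the cells libraries. The neutrophil attractant Cxcl1 stood at 237 ± 43.9 CPM in WT and 803 ± 321 in CKO mural cells, against 335 ± 75.8 and 698 ± 167 in fibroblasts (SD, n = 3 each), and in both classes the libraries of the genotypes did not overlap (exact permutation p = 0.1, the smallest 3 against 3 libraries can give). Il6, a cytokine of the acute phase, stood at 23.7 ± 13.1 CPM in WT and 111 ± 75.6 in CKO mural cells, where the libraries overlapped. In nuclei both genes were close to the floor in mural cells, with 3 to 13 UMIs per genotype. In fibroblast nuclei Il6 stood at 3.03 ± 1.33 CPM in WT and 1.79 ± 1.73 in the libraries labelled CKO, from 44 and 12 UMIs. Cxcl1 stood there at 4.83 ± 1.29 and 6.09 ± 5.81 CPM, from 65 and 46 UMIs. The genotypes overlapped for both, so the rises of fibroblast cells were not seen in fibroblast nuclei, on these few UMIs. Lymphocytes were found as classes in the cells libraries alone. T cells made up 1.44% ± 0.230 of WT and 2.62% ± 0.371 of CKO cells, and B cells 0.330% ± 0.196 and 1.42% ± 1.22, the last from 2.82% in CKO replicate 1 and 0.787% and 0.644% in replicates 2 and 3. Neither class had an overlap of the libraries (exact permutation p = 0.1 for each, the smallest possible; not adjusted over classes). Live sorting and the deeper CKO cells can set these shares.

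Genes that tell the sexes apart did not follow the groups. In the cells libraries Xist, the RNA that silences an X chromosome in females, stood at 587 to 737 CPM in 5 libraries and at 0.0558 CPM in CKO replicate 3, where the Y-linked Ddx3y stood at 66.1 CPM. In nuclei Ddx3y stood at 101 CPM in WT replicate 1 and at 89.3 and 69.0 CPM in CKO replicates 1 and 2, with Xist at 0.472, 0.945 and 0.700 CPM; in WT replicates 2 and 3 and CKO replicate 3 Xist stood at 912, 974 and 630 CPM. The sex of the animals is not in the labels used here, and it was not fitted as a term. The 3 WT nuclei libraries share a title number. Y-linked RNA in WT replicate 1 and Xist in WT replicates 2 and 3 argue against 1 animal for all 3. Whether WT nuclei replicates 2 and 3, or the cells libraries with a shared number, came from separate animals stays open.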
